A study of Mus musculus with 6 samples.

How the data were processed

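RNA was measured in 6 libraries of regulatory T cells (Tregs) from lymph nodes of C57Bl/6 mice immunised with myelin oligodendrocyte glycoprotein (MOG). 3 libraries came from wild-type (WT) mice and 3 from mice without MOG (MOG KO). Per the labels' protocols, total RNA from 500 cells was copied into cDNA with the SMARTer V3 kit, amplified by 15 cycles of PCR, tagged with NexteraXT and read as single reads of 100 bases on a HiSeq 1000. This chemistry carries no molecular identifiers, so copies of 1 molecule made by PCR cannot be told from separate molecules, and the floors and the counting intervals of pooled ratios cover counting error only. The labels number the replicates within each genotype and do not say whether each number is a separate mouse, so p-values measure the spread between these samples, part of which may be technical.

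The deposited count table holds whole-number counts of reads in exons per gene, not normalised, with 1 column per library. The deposited RPM table holds the same data as reads-per-million (RPM) values, and rescaling each count column by its total gave those values with differences under 1e-06. STAR 2.3.1 and R 3.2.2 are named, with genome build mm10, per the submitters' processing notes. The counting function, the gene models, the strand setting and the treatment of reads matching several places are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies may therefore share reads, and values of the globin, heat shock, class I major histocompatibility (H2-T and H2-Q) and ribosomal protein genes are uncertain for that reason. The table lists 23725 genes by Entrez identifier and symbol, 1 of them without a symbol, and 11408 had 0 counts in all 6 libraries. Coordinates are those of GRCm38, the assembly that mm10 names, and 65 genes were matched to it by identifier.

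Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as design, which left 4088 genes (17.2% of the table). Library sizes were scaled by the trimmed mean of M-values (TMM), dispersions and the quasi-likelihood fit were robust, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The model held the genotype alone. Log2 fold changes are MOG KO minus WT. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic of the same fit. It is approximate, above all for genes near 0 in a group. The 95% intervals use that SE with the moderated degrees of freedom of edgeR and so carry the spread between libraries. Totals, detected genes and shares of counts were compared with exact two-sided permutation tests of the difference of means, whose smallest p is 0.1 for 3 samples against 3. A gene is called present in a library at 10 RPM or more. The floor of a library is the RPM of 3 counts, the upper limit that a count of 0 allows.

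33 gene lists, the main tests, the rule for naming genes and the alternatives not named as added were fixed before the data were examined. 20 lists had at least 5 tested members and were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over those lists. Camera with an estimated correlation, and fry, were alternatives. Genes are named by this rule. Mog, Foxp3, Il2ra, Ctla4 and Ikzf2 are named whatever their values. Up to 12 genes per direction are named among those past the threshold with a mean log2 CPM of at least 3 and all 3 libraries of one group above all 3 of the other. Where fewer than 5 qualify in a direction, the genes of smallest unadjusted p that meet the other conditions fill up to 5, leaving out predicted and clone names. Of each list, up to 4 members past the threshold are named, or the 2 of smallest unadjusted p where none passes. Some genes that this rule names are not reported here.

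The fitting steps were tested on simulated counts made from these libraries' means and totals, with 200 genes changed by known folds. Counts were drawn from a negative binomial distribution, and the spread of these libraries was taken as the dispersions that edgeR estimated. Presence in some libraries and near absence in others was not built in as such. For the comparison of MOG KO with WT at low spread (4085 genes), edgeR recovered 100% of the 4-fold and 100% of the 64-fold changes, with 8 false calls. With the spread of these libraries (3777 genes) it recovered 0% of the 4-fold and 27% of the 64-fold changes, with 0 false calls. DESeq2 in the latter simulation recovered 0 of 100 and 49 of 100 genes, with 104 false calls. A simulated list of 4-fold shifted genes had an unadjusted camera p of 0.0147 at that spread, and an unshifted list 0.966. The real lists are judged after adjustment over 20 lists, so this p does not show that a list shifted so would pass.

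Alternatives were DESeq2 size factors in edgeR, no filter on low counts, a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, a replicate block, limma on log2(RPM + 1) and log2(RPM + 0.1), an adjusted p threshold of 0.1, and leaving out each library in turn. DESeq2 on the genes that pass filterByExpr, and camera with an estimated correlation on the libraries left after leaving out 1, were added after seeing the data. Detection was also taken at 10 counts and after thinning every library to the smallest total, and shares of counts also without the most abundant gene of each list. Figures were drawn with matplotlib 3.10.9.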

Results

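Tregs, the CD4 T cells that restrain immune responses, were compared between genotypes in mice immunised with MOG, a protein on the surface of myelin, the sheath around nerve fibres. In WT mice MOG is a self protein, and in MOG KO mice it is absent from the whole animal. The data are gene counts from 3 WT and 3 MOG KO libraries of 500 lymph node Tregs each. Gene counts totalled 2717969, 4472549 and 3527942 in WT replicates 1, 2 and 3, and 4327491, 4361315 and 3450623 in MOG KO replicates 1, 2 and 3. Below, values per library are in reads-per-million (RPM), in that order of replicates, WT before MOG KO.

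The targeted gene, Mog (Entrez 17441, GRCm38 chromosome 17, 37010740 to 37023398), had 1 count over all 6 libraries, in WT replicate 1 (0.368 RPM). The other 5 libraries had 0 counts, which allows up to 0.671 to 0.869 RPM depending on the library. Mog was at or under this floor in both genotypes, so its counts do not check the genotype labels.

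The genes that define Tregs were read in both genotypes, and none of 4 named beforehand passed the test. Foxp3, the transcription factor of the Treg lineage, had 690, 400 and 8.22 RPM in WT and 476, 444 and 326 RPM in MOG KO, a log2 fold change of 0.18 ± 1.34 (SE, n = 3 per group) with a 95% interval of -2.94 to 3.3. Il2ra, the high-affinity interleukin 2 receptor chain, had 654, 739 and 708 RPM in WT and 777, 849 and 371 RPM in MOG KO (-0.14 ± 0.48, 95% interval -1.25 to 0.97). Ctla4, an inhibitory receptor, had 612, 450 and 74.3 RPM in WT and 537, 518 and 502 RPM in MOG KO (0.45 ± 0.89, 95% interval -1.62 to 2.52). Ikzf2, which encodes Helios, had 1180, 580 and 1290 RPM in WT and 1030, 1160 and 909 RPM in MOG KO (-0.06 ± 0.41, 95% interval -1.02 to 0.9). The adjusted p in edgeR was 1 for all 4 genes. Each value changed sign when 1 library was left out, Foxp3 to -0.37, Ctla4 to -0.01 and Ikzf2 to 0.25 without WT replicate 3, and Il2ra to 0.16 without MOG KO replicate 3.

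These genes lie at chromosome X, 7579676 to 7595243 (Foxp3, Entrez 20371), chromosome 2, 11642792 to 11693194 (Il2ra, 16184), chromosome 1, 60909025 to 60915832 (Ctla4, 12477) and chromosome 1, 69531207 to 69687351 (Ikzf2, 22779), all on GRCm38 and all protein-coding.

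Across all 4088 genes tested in edgeR, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.602. At an unadjusted p under 0.05 there were 209 genes, where 204.4 are expected with no difference. The median SE was 2.42 on the log2 scale, and 0.93 among the 500 genes of highest mean, of which 21 had an unadjusted p under 0.05 where 25 are expected. By other tools, DESeq2 put 745 genes past the threshold (271 higher and 474 lower in MOG KO, 543 of them not among the genes tested in edgeR), DESeq2 on the genes tested in edgeR, of which it gave 3511 a p-value, 210 (97 higher and 113 lower), and limma-voom 0.

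The 5 genes of smallest p in each direction, among those whose groups did not overlap, were read at 97.1 RPM or more in all 3 libraries of one genotype and near 0 in the other. Higher in MOG KO by value were Tsnax, an RNA-binding partner of translin (2.58, 0.671 and 0.85 RPM in WT, 582, 405 and 542 RPM in MOG KO, log2 fold change 8.47 ± 1.94), and Ppm1f, a protein phosphatase (1.47, 0.224 and 0.567 RPM, then 358, 633 and 350 RPM, 9.12 ± 2.18). Ttf1, a termination factor of ribosomal RNA transcription, had a log2 fold change of 8.79 ± 2.16, and Dnaaf5, a dynein assembly factor, 8.95 ± 2.29. Nid2, a basement membrane protein, had 3 WT counts against 4068 in MOG KO, a pooled WT over MOG KO ratio of 0.000835 with a counting interval of 0.000172 to 0.00244. Lower in MOG KO by value were Zfp646, a zinc finger gene (677, 308 and 729 RPM in WT, 0.693, 0.459 and 0.58 RPM in MOG KO, log2 fold change -9.96 ± 1.77), and Arhgap15, a regulator of Rac GTPases (438, 461 and 599 RPM, then 1.85, 2.29 and 2.03 RPM, -7.97 ± 1.79). Usp33, a deubiquitinase, had -10.06 ± 2.1, Unc119b, a carrier of lipid-modified proteins, -9.48 ± 2.15, and Ankle2, a factor of nuclear envelope assembly, -9.87 ± 2.32. None of these 10 genes passed the test (adjusted p = 0.602 for each in edgeR).

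**Figure D1:**
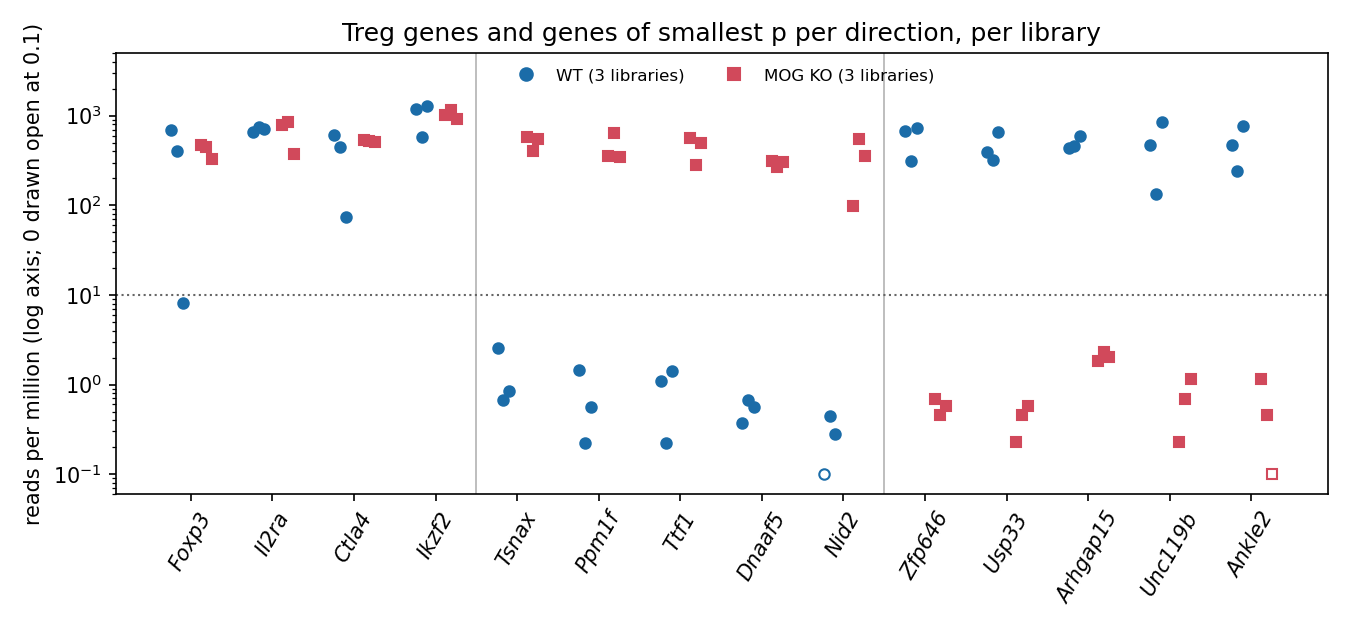
RPM (log axis) in each library for 4 Treg genes and the 5 genes of smallest p in each direction among those whose groups did not overlap, with WT libraries as circles and MOG KO libraries as squares; values of 0 are drawn open at 0.1 and the dotted line marks 10 RPM. Foxp3 in WT replicate 3 is at 8.22 RPM, and the 10 other genes are at 97.1 RPM or more in one genotype and under 3 RPM in the other.

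These 10 genes are protein-coding on GRCm38. Tsnax (Entrez 53424) lies on chromosome 8 from 125013041 to 125034208, Ppm1f (68606) on chromosome 16 from 16896469 to 16927375, Ttf1 (22130) on chromosome 2 from 29060199 to 29087656, Dnaaf5 (433956) on chromosome 5 from 139150133 to 139186510 and Nid2 (18074) on chromosome 14 from 19751257 to 19811787. Zfp646 (233905) lies on chromosome 7 from 127876914 to 127885996, Usp33 (170822) on chromosome 3 from 152346184 to 152393617, Arhgap15 (76117) on chromosome 2 from 43748798 to 44395953, Unc119b (106840) on chromosome 5 from 115122566 to 115134975 and Ankle2 (71782) on chromosome 5 from 110231004 to 110256651.

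Most genes were read in some libraries and were near 0 in the others. Of 7909 genes present in at least 1 library, 704 (8.9%) were present in all 6 and 2537 in 1 library. Over the 7909 genes, 3.09% of the values per library lay between 3 and 10 RPM. Pairs of libraries of the same genotype differed in the presence of 3286 ± 184 genes (SD, 6 pairs), and pairs of different genotype in 3288 ± 161 genes (9 pairs). WT libraries had at least 1 count for 7696 ± 1140 genes and MOG KO libraries for 7350 ± 1070 (SD, n = 3 per group, exact two-sided permutation p = 0.5). Total counts were 3573000 ± 878000 and 4046000 ± 516000 (exact p = 0.7), and genes at 10 RPM or more differed with an exact p of 0.7. WT replicate 3 had the fewest genes present, 2701, against 3265 to 4440 in the other 5 libraries.

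**Figure D2:**
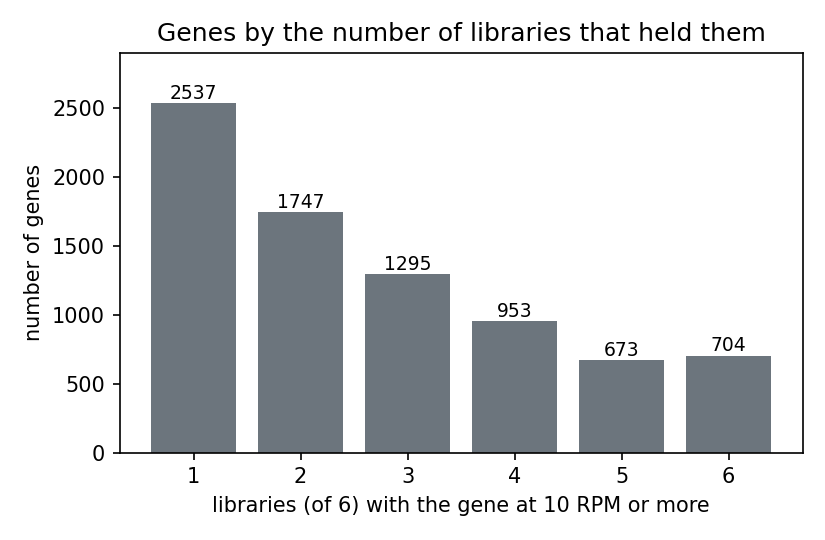
Number of genes (vertical axis) by how many of the 6 libraries held them at 10 RPM or more (horizontal axis). The bars fall from 2537 genes in 1 library to 673 in 5, with 704 in all 6.

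The groups that describe Treg identity and function had 0 members past the threshold. Of the Treg core signature, 12 of 25 genes were present in all 6 libraries. Among its 18 tested members 0 passed, 7 had positive and 11 negative values, the median was -0.1 and the camera adjusted p 0.656. Nrp1, a surface receptor, was read in every library (817, 655 and 1150 RPM in WT, 570, 133 and 397 RPM in MOG KO, log2 fold change -1.35 ± 0.65). Ikzf4, which encodes Eos, had 546, 104 and 0 RPM in WT and 32.8, 0 and 0 RPM in MOG KO. Of 23 effector Treg genes 0 passed, 14 were positive and 9 negative (median 0.18, camera adjusted p 0.486). Cxcr6, a chemokine receptor, had 1.84, 164 and 1.7 RPM in WT and 413, 338 and 468 RPM in MOG KO, and Gzmb, which encodes granzyme B, had 234, 230 and 1.98 RPM and 456, 449 and 693 RPM. Of 13 suppressive mediators, which include Nrp1 again, 0 passed, 6 were positive and 7 negative (median -0.03, camera adjusted p 0.744). Cd274, which encodes the ligand PD-L1, had 529, 401 and 120 RPM in WT and 1.16, 94.2 and 0.58 RPM in MOG KO (log2 fold change -3.44 ± 2.35).

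Genes of resting and conventional T cells held the transcription factor gene Tcf7, at 285, 333 and 93.8 RPM in WT and 0.693, 1.15 and 1.74 RPM in MOG KO (log2 fold change -7.6 ± 2.28, adjusted p = 0.602 in edgeR). Among 12 tested resting lymphoid genes 0 passed, with 5 positive and 7 negative (median -0.48, camera adjusted p 0.486). Ccr7, a lymph node homing receptor, had 7.36, 2.68 and 243 RPM in WT and 1.85, 2.29 and 2.32 RPM in MOG KO. Among 6 tested conventional CD4 T cell genes 0 passed, with 3 positive and 3 negative, a median of -0.53 and a mean of -2.46. Its camera p was 0.0487 before and 0.486 after adjustment, and 0.181 before adjustment with an estimated correlation. Sidt1, the other named member, had 28.3, 386 and 75.4 RPM in WT and 0.231, 0 and 0.869 RPM in MOG KO (adjusted p = 0.65 in edgeR). All 6 tested helper T cell cytokines and regulators had negative values and 0 passed (median -1.45, camera adjusted p 0.486). This depended on single libraries, with 3 of 7 members positive without WT replicate 2 (median -0.39, camera adjusted p 0.994). Without MOG KO replicate 3, 0 of 6 were positive (median -2.6, camera adjusted p 0.524). Rora, a nuclear receptor of helper cells, had 854, 252 and 338 RPM in WT and 399, 2.98 and 5.22 RPM in MOG KO, and Il6st, the shared signalling chain of the interleukin 6 family, 698, 635 and 1.42 RPM and 15.5, 1.38 and 432 RPM.

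Genes of antigen receptor signalling and inflammation also had 0 members past the threshold. Among 21 immediate genes of T cell receptor activation, 6 were positive and 15 negative (median -0.36, camera adjusted p 0.656). Of these, Egr1 had 4.05, 37.3 and 349 RPM in WT and 0.693, 0.917 and 1.16 RPM in MOG KO (adjusted p = 0.75 in edgeR), and Jun 36.8, 32.2 and 1.13 RPM and 553, 21.3 and 405 RPM. Among 25 genes of the T cell receptor signalling machinery, 12 were positive and 13 negative (median -0.09, camera adjusted p 0.688). Ptpn22, a phosphatase that restrains receptor signalling, had 2796 counts in WT and 1 in MOG KO, a pooled ratio of 3170 with a counting interval of 568 to 125000 (adjusted p = 0.602 in edgeR), and Ptpn6, another phosphatase, had 142 RPM in WT replicate 2 and 2.03 to 5.52 RPM elsewhere. Among 18 genes of NF-kB and the TNF receptor family, 8 were positive and 10 negative (median -0.27, camera adjusted p 0.527). The NF-kB subunit gene Relb had 378, 211 and 456 RPM in WT and 0.231, 1.38 and 0.58 RPM in MOG KO (-8.9 ± 2.29, adjusted p = 0.602 in edgeR), and Nfkb1 387, 34 and 86.2 RPM and 37, 0.229 and 2.32 RPM. Among 17 interferon-stimulated genes, 12 were positive and 5 negative (camera adjusted p 0.527). Usp18, a negative regulator of interferon signalling, had 242, 215 and 27.8 RPM in WT and 0 counts in all 3 MOG KO libraries (adjusted p = 0.602 in edgeR). Against a floor of 3 counts over the group this is at least 648-fold lower, a bound that covers counting error and not the spread between libraries. With Usp18 at this bound the list's median stayed at 0.15. Stat2 had 9.2, 21 and 0.283 RPM in WT and 456, 777 and 0.58 RPM in MOG KO. Among 14 genes of the interleukin 2 and STAT5 response, 4 were positive and 10 negative (median -0.06, camera adjusted p 0.953). Pim1, a kinase gene of that response, had 127, 85.2 and 0.567 RPM in WT and 462, 524 and 581 RPM in MOG KO, and Stat5b 489, 672 and 0.85 RPM and 123, 23.6 and 0.29 RPM.

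Among 21 homing receptors and integrins, 0 passed, 7 were positive and 14 negative (median -0.17, camera adjusted p 0.688). Beside Ccr7, the named member was Gpr183, an oxysterol receptor that guides lymphocytes, at 236, 34 and 401 RPM in WT and 38.4, 21.8 and 9.85 RPM in MOG KO (-3.4 ± 2). Among 13 cell cycle genes, 0 passed, 3 were positive and 10 negative (median -0.91, camera adjusted p 0.486). Stmn1, a microtubule regulator of dividing cells, had 7.73, 78 and 2360 RPM in WT and 2.77, 271 and 165 RPM in MOG KO, and the mitotic kinesin gene Kif20a 0, 229 and 366 RPM and 0, 17.9 and 0 RPM. The log2 fold change of Stmn1, -2.63 ± 2.06, was 1.82 without WT replicate 3. WT replicate 3 had 1.03% of its counts in the cell cycle list, and the other 5 libraries 0.19% to 0.482%. Without WT replicate 1 the list was past the threshold (20 members, 3 positive, camera adjusted p 0.00379). Camera with an estimated correlation gave p = 0.0267 before and 0.534 after adjustment. That correlation was -0.012, below the preset 0.01, so correlated members do not account for the higher p. Without WT replicate 3, 10 of 19 members were positive, with a median of 0.03 (camera adjusted p 0.945).

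Ribosomal protein genes were the most evenly read group, with 66 of 85 present in all 6 libraries. Among 79 tested, 56 were positive and 23 negative (median 0.36), and 0 passed. The camera p was 0.0337 before and 0.486 after adjustment, and p = 0.551 with an estimated correlation. Rpl23a had 210, 301 and 391 RPM in WT and 750, 436 and 730 RPM in MOG KO (log2 fold change 1 ± 0.72). Without WT replicate 3, 70 of 79 members were positive and the list was past the threshold (camera adjusted p 0.00576), and adjusted p = 0.914 with an estimated correlation. Without WT replicate 1, 44 of 80 members were positive, with a median of 0.07 (camera adjusted p 0.796).

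Metabolic and stress genes had 0 members past the threshold. Among 45 genes of oxidative phosphorylation, 31 were positive and 14 negative (median 0.21, camera adjusted p 0.527). The complex I gene Ndufc2 had 689 counts in WT and 2 in MOG KO (pooled ratio 390, counting interval 108 to 3230, adjusted p = 0.645 in edgeR), and the complex II gene Sdha had 5.52, 121 and 0.85 RPM in WT and 463, 474 and 649 RPM in MOG KO. Among 14 glycolysis genes, 7 were positive and 7 negative (median 0.02, camera adjusted p 0.896). Of these, Hif1a had 353, 536 and 1.7 RPM in WT and 809, 793 and 510 RPM in MOG KO, and Pgk1 33.8, 365 and 0.85 RPM and 40.7, 0 and 0.869 RPM. Among 6 genes of cholesterol synthesis, 4 were positive and 2 negative (camera adjusted p 0.956). Srebf2, a regulator of the pathway, had 3.68, 94.1 and 0.85 RPM in WT and 59.2, 256 and 188 RPM in MOG KO. Among 21 genes of the unfolded protein response and heat shock, 14 were positive and 7 negative (median 0.27, camera adjusted p 0.56). Hspa8, an abundant chaperone, had 3180, 3830 and 4680 RPM in WT and 5950, 5160 and 4600 RPM in MOG KO (0.35 ± 0.2, 95% interval -0.12 to 0.82), and Hspa1a 9.2, 2.68 and 467 RPM and 485, 959 and 1070 RPM. Among 8 genes of apoptosis and the p53 response, 3 were positive and 5 negative (camera adjusted p 0.953). The death gene Bcl2l11 had 2.58, 9.84 and 0.567 RPM in WT and 476, 25.7 and 0.869 RPM in MOG KO, and Trp53inp1 1390, 358 and 383 RPM and 705, 31.4 and 328 RPM.

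Genes beside a knocked-out locus can carry the sequence of the strain in which it was targeted. Among 15 of these neighbours tested, 0 passed, 10 were positive and 5 negative (median 0.46, camera adjusted p 0.527). H2-T10 had 72.8, 201 and 172 RPM in WT and 587, 611 and 333 RPM in MOG KO, and H2-T24 had 0.368, 283 and 253 RPM and 28.7, 5.73 and 3.19 RPM. Both belong to a family of near-identical genes.

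**Figure D3:**
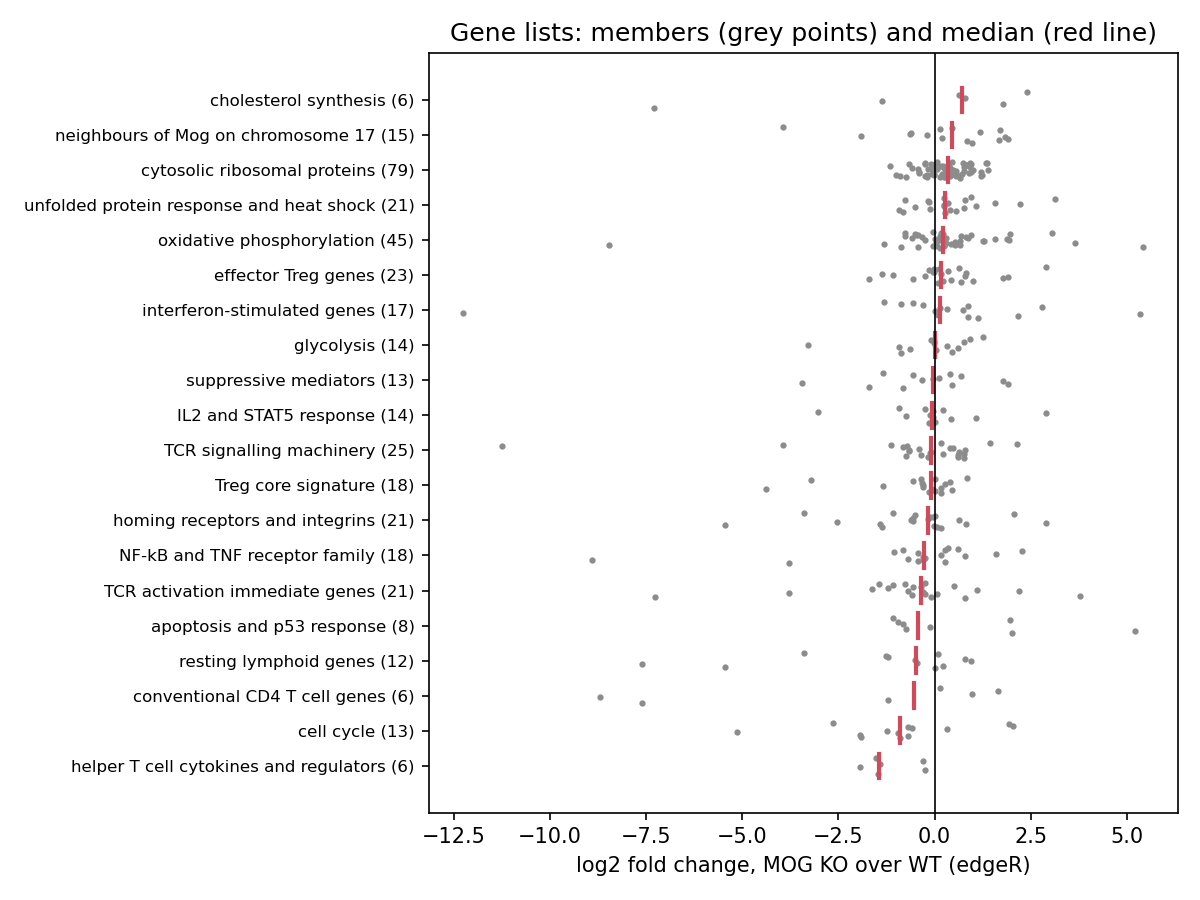
Log2 fold changes of MOG KO over WT in edgeR (horizontal axis) for the tested members of each of 20 gene lists (grey points, number of members in brackets) with the median of each list (red line). Medians run from -1.45 in helper T cell cytokines and regulators to 0.71 in cholesterol synthesis, and 0 members and 0 lists passed the test.

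Over all lists together, 374 genes were tested and 0 passed, also when adjusted over the list alone for each list, and 0 of 20 lists passed camera. Fry gave an unadjusted p under 0.05 for resting lymphoid genes only (0.0247, adjusted 0.493). Its mixed p, for change in either direction, was under 0.05 before adjustment for conventional CD4 T cell genes (0.00668), T cell receptor signalling (0.00913), cholesterol synthesis (0.0249) and NF-kB and the TNF receptor family (0.0414), and the smallest adjusted mixed p was 0.0913. The median, the mean and the direction of camera differed in sign for the interleukin 2 and STAT5 list (-0.06, -0.05, up), interferon-stimulated genes (0.15, -0.05, up), cholesterol synthesis (0.71, -0.51, down), glycolysis (0.02, -0.11, up) and apoptosis (-0.43, 0.68, down). As a share of all counts, 3 of 31 lists with a member in the table reached the smallest exact permutation p of 0.1, where 3.1 are expected. These were oxidative phosphorylation (0.401% ± 0.0702 in WT and 0.555% ± 0.0472 in MOG KO, SD, n = 3 per group), the unfolded protein response and heat shock (0.896% ± 0.187 and 1.23% ± 0.0691) and red cell markers (0.011% ± 0.00408 and 0.00399% ± 0.00245). Without its most abundant gene the difference of the red cell list was -0.00174% (exact permutation p = 0.4). Oxidative phosphorylation without its most abundant gene held 0.368% in WT and 0.519% in MOG KO (exact permutation p = 0.1). The unfolded protein response and heat shock list, treated alike, held 0.506% and 0.702% (exact permutation p = 0.1).

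Markers of other cells took small shares of the counts. B cell markers held 0.0273% ± 0.0164 in WT and 0.0208% ± 0.00941 in MOG KO (exact permutation p = 0.7), and their class II members were near 0 (H2-Ab1, 0.447 to 3.48 RPM) while Cd74, the invariant chain gene, had 280, 217 and 8.5 RPM in WT and 173, 179 and 124 RPM in MOG KO. Plasma cell markers held 0.0196% ± 0.018 and 0.00981% ± 0.0168 (exact p = 0.5), led by Xbp1, which T cells also express (216, 358 and 1.98 RPM, then 0.462, 292 and 0.869 RPM). CD8 T cell markers held 0.0051% ± 0.00463 and 0.00711% ± 0.00707 (exact p = 0.7), led by the chemokine gene Ccl5 (90.1, 62.4 and 0 RPM, then 0, 71.3 and 141 RPM). Macrophage and dendritic cell markers held 0.0354% ± 0.0162 and 0.0367% ± 0.00774 (exact p = 0.8). In that list Cd68 had 188 RPM in MOG KO replicate 2 and 0.693 to 5.89 RPM elsewhere, and Lyz2 had 2.91 to 9.57 RPM. Neutrophil markers held 0.011% ± 0.0159 and 0.0193% ± 0.0324 (exact p = 0.9), and stromal and endothelial markers 0.00445% ± 0.00523 and 0.0183% ± 0.0241 (exact p = 0.5), led by Pecam1, which T cells also express (461 RPM in MOG KO replicate 1 and 1.98 to 89.4 RPM elsewhere). NK cell markers held 0.000127% ± 0.000113 and 4.43e-05% ± 4.35e-05 (exact p = 0.4), and gamma delta T cell markers 2.92e-05% ± 7.25e-06 and 7.64e-06% ± 1.32e-05 (exact p = 0.2). The globin genes Hba-a2 and Hbb-bt had log2 fold changes of -1.73 ± 1.84 and -1.15 ± 1.8.

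Of 12 myelin genes, 2 were tested and 0 passed. Cnp, an enzyme of myelin-forming cells that lymphocytes also express, had 568, 375 and 448 RPM in WT and 608, 589 and 698 RPM in MOG KO (0.39 ± 0.56, 95% interval -0.9 to 1.68), and Mbp 6.25, 249 and 1.13 RPM and 1.16, 380 and 1.45 RPM. The list held 0.0552% ± 0.00898 of counts in WT and 0.076% ± 0.0187 in MOG KO (exact permutation p = 0.2). Of the sex-linked genes, Ddx3y had 0.368, 4.92 and 0 RPM in WT and 517, 0.459 and 175 RPM in MOG KO, and Eif2s3y 1.84, 125 and 365 RPM and 0.693, 82.3 and 354 RPM, with 0 of 2 past the test and a share of 0.0172% ± 0.0177 and 0.0572% ± 0.0511 (exact p = 0.3). The lists of mitochondrially encoded genes and of T cell receptor variable segments had 0 members in the table and were not analysed here.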

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

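DESeq2 on the filtered genes, and the estimated correlation with 1 library left out, were chosen after the result was seen. The other alternatives were planned. The count of genes past the threshold was 0 in edgeR under every setting run there (DESeq2 size factors, no filter, the strict filter, an adjusted p of 0.1, each library left out) and 0 in limma-voom with or without sample weights and in limma on RPM. It was 745 in DESeq2 (271 higher, 474 lower) and 210 in DESeq2 on the filtered genes (97 higher, 113 lower). DESeq2 also made calls outside the genotype comparison. At the spread of these libraries it made 104 false calls in the simulation, where edgeR made 0, and the other 9 splits of the libraries gave 188 to 262 calls in DESeq2 on the filtered genes. The simulated spread was the one edgeR estimated, which may favour edgeR in the simulation. With 1 library left out the smallest adjusted p in edgeR was 0.0659, without MOG KO replicate 3. Of the genes named by the rule, 19 passed the threshold in DESeq2 and 19 in DESeq2 on the filtered genes, all with the direction given in edgeR. TMM and DESeq2 size factors gave median log2 fold changes of 0.063 and 0.057 over all tested genes.

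No pairing of the samples by replicate number was seen. Same-numbered libraries had deviations from their group means that correlated at -0.022, -0.002 and -0.018. In log2 CPM of the 4088 tested genes, pairs of libraries correlated at only 0.133 to 0.224, also within a genotype. A shared day or litter could therefore go unseen. A fit with the replicate block called 0 genes (143 at an unadjusted p under 0.05) and 0 lists.

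Some log2 fold changes with intervals that span 0 changed sign, and the cause was not tested. Ikzf2 was 0.55 in limma-voom, 0.56 with sample weights, 0.03 with the replicate block and 0.10 in limma on log2(RPM + 1) and on log2(RPM + 0.1). H2-Ab1 was 0.04 in limma-voom, 0.10 with the block, and 0.02 and 0.14 on RPM with pseudocounts of 1 and 0.1. Cd74 was 0.07 with DESeq2 size factors, 0.15 in DESeq2, 0.07 in DESeq2 on the filtered genes, 0.79 in limma-voom, 0.70 with the block, and 0.92 and 0.96 on RPM with pseudocounts of 1 and 0.1. Mbp was -0.62 in limma-voom, -0.73 with sample weights, -0.47 with the block, and -0.31 and -0.47 on RPM with pseudocounts of 1 and 0.1. With sample weights Stmn1 was 0.53, Hspa8 -0.14, Ccl5 -1.23 and Eif2s3y 1.05, and with the block Cd68 was -0.13.

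Leaving out 1 library at a time gave ranges of -0.37 to 1.03 for Foxp3, -0.38 to 0.16 for Il2ra, -0.01 to 0.97 for Ctla4, -0.33 to 0.25 for Ikzf2, -3.46 to 1.82 for Stmn1, -0.81 to 0.28 for H2-Ab1, -0.62 to 0.5 for Cd74, -0.44 to 1.19 for Ccl5, -1.46 to 4.92 for Cd68, -0.04 to 3.74 for Pecam1, -2.09 to 1.23 for Eif2s3y and -5.93 to 5.1 for Mbp. The number of lists past the threshold ranged from 0 to 1. It was 1 without WT replicate 1 (cell cycle, camera adjusted p 0.00379) and 1 without WT replicate 3 (ribosomal proteins, 0.00576), and 0 with an estimated correlation (all libraries or 1 left out), fry, the replicate block, DESeq2 size factors or the strict filter. Mog counts over the libraries ranged from 0 to 1.

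The difference in detected genes, MOG KO minus WT, was -346 at 1 count, -327 at 10 counts and -683 after thinning. Without its most abundant gene, the difference in share of counts turned to -0.0105% for neutrophil markers and -7.5e-05% for stromal and endothelial markers. It became 0% for gamma delta T cell markers and -0.00174% for red cell markers. It kept its sign for the other 6 lists of other cells, conventional CD4 T cells included. The share of suppressive mediators turned too, from 0.382% in WT and 0.354% in MOG KO to 0.295% and 0.317%. The planned setting without immune receptor segments was not run, since the table used here held 0 such segments. With the spread of these libraries the simulated 4-fold changes were recovered at 0% in edgeR. Genes differ in precision, with a median SE of 2.42 over all tested genes and 278 genes under 1.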

Other observations

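Chosen only after the result was seen were the test of few captured molecules, the test of resting conventional CD4 T cells, the count of splits for edgeR, and the genes of the next 2 paragraphs.

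Of the listed genes tested in edgeR, 20 had an SE of 0.5 or less, and these bound the difference between genotypes most closely. Among receptors of the interleukin 2 family, Il2rb had a log2 fold change of 0 ± 0.44 (SE, n = 3 per group, 95% interval -1.03 to 1.02) and Il2rg -0.07 ± 0.45 (-1.12 to 0.98), and their kinase gene Jak1 -0.05 ± 0.38 (-0.95 to 0.84). The costimulatory receptor gene Icos had 0.1 ± 0.32 (-0.63 to 0.83), and Cd6 0.18 ± 0.37 (-0.68 to 1.04). Of the integrin genes, Itgb7 had -0.17 ± 0.34 (-0.97 to 0.62) and Itgal -0.55 ± 0.41 (-1.5 to 0.39). A 4-fold difference lies outside the intervals of these 7 genes, whereas for Foxp3 and Ctla4 it does not.

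The cytokine genes Ifng, Il4, Il5, Il13, Il17a, Il17f, Il21, Il22 and Csf2 had 0 counts in all 6 libraries, which allows up to 0.671 to 1.1 RPM each, and Il10 had 0.229 RPM in MOG KO replicate 2 and 0 elsewhere. Gata3, a transcription factor that Tregs also express, was present in every library (319, 337 and 564 RPM in WT, 245, 340 and 495 RPM in MOG KO). The actin gene Actg1, among the most abundant, had 4728 to 13830 RPM. Gvin1, a large interferon-inducible GTPase gene, had 1927 to 7650 RPM in 5 libraries and 28.98 RPM in MOG KO replicate 3. Of the Y-linked genes, Eif2s3y was present in 4 libraries, Ddx3y in 2, Kdm5d in 1 and Uty in 1. At least 1 of them was present in each of the 6 libraries, and Xist had 2 counts in all.

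Most genes were present in some libraries and near 0 in others (7205 of 7909, or 91.1%). A difference between genotypes is argued against as the main source of this pattern, since pairs of different genotype differed in the presence of only 0.0676% more genes than pairs of the same genotype. After thinning every library to the smallest total, 98.9% of the genes present in 1 to 5 libraries kept the same libraries. Presence is set in RPM, which thinning leaves unchanged on average, so this result could hardly differ. It does not decide whether a difference in depth plays a part. Few captured RNA molecules per library stay open and untested. Of the oxidative phosphorylation genes, which all these cells use, 67.3% (35 of 52) were present in 1 library and under 10 RPM in another of the same genotype, but 89.5% of all present genes were too, so this restates the pattern. A genotype difference in single genes stays open as well.

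Where a gene was near 0, a few counts often remained. Genes present in 1 library only, and at 100 RPM or more there, had 6.76 to 11.4 counts in the other 5 libraries for every 1000 in that library. Reads crossing between pooled libraries could leave such counts, which would then rise with the count in the source library. The genes in the upper part by count had 1.4 times the stray counts of those in the lower part (median of 6 libraries, range 1.1 to 1.68), for 2.06 to 2.75 times the counts. This lies between the limits set beforehand, at least 1.5 for crossing reads and at most 1.2 against them. In all 6 libraries the stray counts rose by less than the counts, so crossing in proportion to the source would not alone give this. Crossing reads, low true expression and a mix of them cannot be told apart.

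Foxp3 was at 8.22 RPM in WT replicate 3 and at 326 to 690 RPM in the other 5 libraries. Resting conventional CD4 T cells in place of Tregs are argued against, since their list took 0.0278% of counts in that library, below the median of the others, though activated conventional cells were not tested. Random loss may account for it: of 951 genes present in the other 5 libraries, this library lacked 247 (26%, against 5.76% to 14.6% in the others), and of 14 Treg core genes it lacked 2, Cd81 and Foxp3 (one-sided Fisher exact p = 0.914 for a higher loss than in other genes).

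With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In DESeq2 on the filtered genes the real split gave 210 genes and the highest other split 262, and 5 of the 10 splits gave at least as many as the real one. Genes present in all 3 libraries of one group and in none of the other numbered 127 in the real split and at most 167 in another, and 5 of 10 splits gave as many. In edgeR the real split gave 0 genes and the highest other split 1, and for lists 0 and 2. With a real count of 0 all 10 splits give as many by construction, so these counts say nothing about chance.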
